A study of Danio rerio with 6 samples.

How the data were processed

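RNA was measured in adult zebrafish (Danio rerio) of the transgenic line Tg(slc12a3:mCherry), in which the distal late (DL) segment of the mesonephros, the adult kidney, carries a red fluorescent reporter. Per the labels' protocols, DL segments were dissected by hand, RNA was extracted with a Macherey-Nagel kit and libraries were made with the NuGEN Ovation Single Cell RNA-seq System. The labels put 3 libraries in the DL group and 3 in a group holding the rest of the mesonephros. Replicate numbers follow the order of deposition and were not used to pair libraries. The labels do not say whether the libraries came from separate animals, or whether DL and rest libraries came from the same fish, so p-values measure only the spread between these samples, which may be technical.

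The authors deposited 1 table of estimated counts (expected counts, in part fractional and kept to 4 significant digits) for 31953 Ensembl genes. The aligner, the counting tool and the genome build are not given in the sources used here. The deposited counts summed to between 9320756 and 22776825 per library. All 6 columns were assigned to libraries by their names. Symbols came from a table of gene identifiers and matched 26121 genes. Another 5832 genes had none and are given by identifier. A symbol shared with another identifier, the case for 4294 genes, is printed with its identifier where both copies are named. Many symbols in that table are in capitals, as for the orthologous human gene. No genome was used here, so no coordinates are given.

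Counts were rounded to whole numbers. Genes were filtered with filterByExpr by group, which left 17083 genes. Libraries were scaled by TMM, and DL was compared with the rest by the quasi-likelihood F test of edgeR 4.0.16 in R 4.3.3, with robust dispersions and Benjamini-Hochberg adjustment at 0.05. Fold changes are coded as DL minus rest. Their standard errors are the absolute log2 fold change over the square root of F. CPM values are relative to the TMM-scaled library size. TMM factors were 0.52 and 0.53 in DL replicate 1 and rest replicate 3 and between 1.14 and 1.80 in the others. Where a gene had 0 counts in a whole group, the fold is a lower bound against a floor of 3 counts over the group's 3 libraries together. Such floors and intervals cover counting error only, since the reads carry no molecular identifiers.

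Before the data were examined, 29 gene lists were fixed for nephron segments, transport, metabolism, and the other cell types a kidney dissection can hold. Members were matched by exact symbol, or by the capitalised symbol without its copy letter, in which case every gene with that symbol joined. For 5 lists (respiratory chain, junctions, potassium and chloride channels, ribosomal proteins and the mitochondrial genome) members were taken by the start of the symbol instead. Lists were tested with camera in limma 3.58.1 on log-CPM with a prior count of 2 and a preset correlation of 0.01, adjusted over the lists, and again with an estimated correlation. The fry test asks if a list's genes move on balance in 1 direction. Members are also given adjusted over the list alone. Shares of counts were compared by exact two-sided permutation, for which 3 against 3 libraries allow no p below 0.1.

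Genes are named by a rule fixed in advance. It takes slc12a3 (listed as SLC12A3); among genes past the threshold with a mean log-CPM of at least 5, no overlap between groups and a symbol that is not a clone name, up to 12 per direction by fold change; and for each list the 2 members with the smallest adjusted p per direction plus its most abundant member. Other genes are marked as chosen after their values were seen. Not every gene that this rule takes is reported here. Tandem copies (atp1a1a.1 to atp1a1a.5, slc12a10.1 to slc12a10.3, slc9a3.1 and slc9a3.2) can share reads, so their separate values are uncertain. Overlapping and antisense genes are likewise uncertain, since no strand setting is given.

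Alternatives were DESeq2 1.42.0, limma-voom with sample quality weights, other scalings, other filters, thinning to the smallest library, leaving out the 20 most abundant genes, a test against a log2 fold change of 1 (glmTreat), and leaving out each library. Chosen after the data were seen were the removal of DL replicate 1 and rest replicate 3 together, a term for them, and DESeq2 without DL replicate 3. The procedure was tested on simulated data for the same comparison, with 17083 genes of which 200 were changed. Each gene was drawn with its own dispersion, and changed genes were taken only from those above a minimum log-CPM. Of 50 genes changed at each size, edgeR recovered 8 at 4-fold, 34 at 8-fold, 46 at 16-fold and 48 at 32-fold, with 6 unchanged genes called. DESeq2 recovered 21, 39, 48 and 49, with 70 unchanged genes called.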

Results

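The data are 6 RNA-seq libraries from the mesonephros of adult Tg(slc12a3:mCherry) zebrafish, 3 from dissected mCherry-positive distal late (DL) segments and 3 from the rest of the organ. Total counts were 13863861, 22776825 and 9320756 in DL replicates 1 to 3 and 18329049, 12279681 and 11109171 in rest replicates 1 to 3. Between 19413 and 21848 genes were detected per library. The comparison asks which transcripts mark the DL segment within the mesonephros.

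The genes slc12a10.3, slc9a3.2, ca4c, TFAP2B, PAX8 and ucp3 were among the 11 genes higher in DL segments than in the rest of the mesonephros by edgeR's quasi-likelihood test. The slc12a10.3 gene, a relative of the sodium-chloride cotransporter, stood at 1115 ± 696 CPM in DL and 30.02 ± 13.36 CPM in the rest (SD, n = 3 each). Its tandem copy slc12a10.2 stood at 11.5 ± 4.5 against 15.6 ± 5.6 CPM and was not called. The sodium-proton exchanger gene slc9a3.2 stood at 737 ± 466 against 19.2 ± 9.99 CPM, and the membrane carbonic anhydrase gene ca4c at 219 ± 159 against 4.59 ± 1.60 CPM. The transcription factor genes TFAP2B and PAX8, both active in the developing nephron, stood at 81.8 ± 55.8 against 2.21 ± 1.02 CPM and at 80.9 ± 40.6 against 6.35 ± 0.603 CPM. The gene ucp3, an uncoupling protein of the inner mitochondrial membrane, stood at 246 ± 127 against 10.23 ± 3.13 CPM.

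In the edgeR test 11 of 17083 genes were higher in DL, each with an adjusted p of 0.0419, and 0 were lower. At an unadjusted p under 0.05 there were 699 higher and 467 lower genes. DESeq2 called 235 higher and 79 lower, and limma-voom 36 higher and 0 lower. In the simulated data DESeq2 called 70 unchanged genes and edgeR 6, so the DESeq2 calls may hold more false ones. The log2 fold changes were 5.58 ± 0.84 (SE) for ca4c, 5.27 ± 0.78 for slc9a3.2, 5.23 ± 0.76 for TFAP2B, 5.21 ± 0.78 for slc12a10.3, 4.59 ± 0.62 for ucp3 and 3.67 ± 0.52 for PAX8. The sodium pump alpha subunit gene atp1a1a.2, which has near-identical tandem copies, had 4.53 ± 0.67. The other 4 genes fell outside the naming rule and were listed after their values were seen. They were hhla2a.1 (5.22 ± 0.74), si:dkey-39a18.1 (3.80 ± 0.50), zgc:158423 (4.88 ± 0.65) and HHATL_ENSDARG00000039051. The last had a log2 fold change of 8.48 ± 1.15, with 736 counts in DL and 2 in the rest. The ratio of rates from these pooled counts was 476, with an exact binomial 95% interval of 131 to 3939. That interval covers counting error only and leaves out the variation between libraries. All 11 had every DL library above every rest library. Across all tested genes 13.1% showed no overlap between groups, where chance gives 10%. The count was 0 without any 1 of DL replicate 1, DL replicate 2, rest replicate 1, rest replicate 2 or rest replicate 3, and 53 without DL replicate 3. It was 1 with library size as the only scaling and 0 without DL replicate 1 and rest replicate 3 together.

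**Figure D1:**
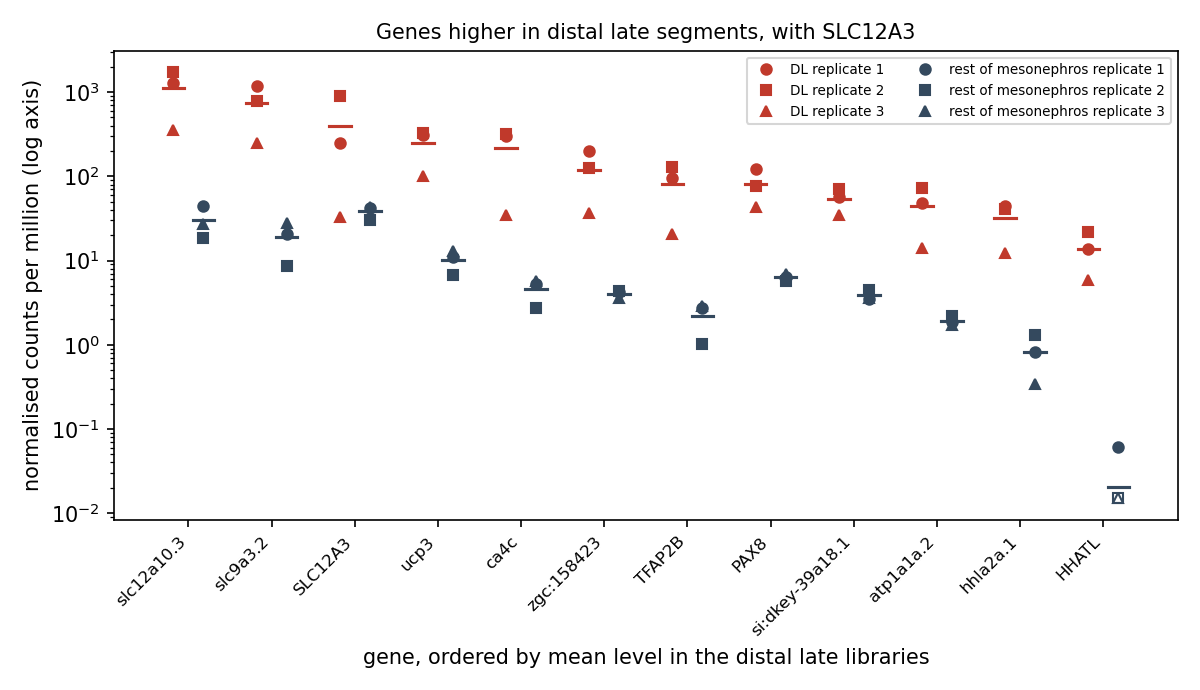
CPM (log axis) of the 11 genes higher in DL and of SLC12A3, with 1 symbol per library, a bar at each group mean, and open symbols at the axis base for 0 counts. DL replicate 3 is the lowest DL library for each gene and lies at 32.9 CPM for SLC12A3, among the rest libraries.

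SLC12A3, the thiazide-sensitive sodium-chloride cotransporter from whose gene the reporter is driven, checks the dissection and is not independent evidence. It stood at 251, 905 and 32.9 CPM in DL replicates 1 to 3 and at 41.9, 30.4 and 43.0 CPM in rest replicates 1 to 3. The library labelled DL replicate 3 thus lay within the range of the rest libraries. The log2 fold change was 3.37 ± 0.92 (SE) and did not pass the edgeR test over all genes (adjusted p = 0.292), although it did when adjusted over the list alone (0.0109). Without DL replicate 3 it was 3.96 with an adjusted p of 0.0439, and in DESeq2 3.38 with 0.00493. Over all alternatives the fold change ranged from 1.89 to 3.96 and the adjusted p from 1.66e-07 to 0.901.

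Of 16 tested genes of distal tubule ion transport, 1 was higher over all genes by edgeR, and 6 were higher and 1 lower adjusted over the list alone. DESeq2 called 5 list members higher and 1 lower. The lower one, egf, was named after its values were seen and was not among the 16 (log2 fold change -7.22 ± 2.13, DESeq2 adjusted p = 0.0462). KCNJ15, a potassium channel, had a log2 fold change of 2.68 ± 0.57. After their values were seen, clcnk and bsnd, a chloride channel and its accessory subunit, were added at 4.05 ± 0.99 and 3.39 ± 0.78. One copy of the sodium-calcium exchanger gene, SLC8A1_ENSDARG00000013422, was lower at -2.03 ± 0.60. The list was called higher by camera (median log2 0.93, adjusted p = 0.00504; adjusted p = 0.555 with an estimated correlation), but not without DL replicate 1 and rest replicate 3 together (adjusted p = 0.102). Of 19 sodium pump genes, 1 was higher over all genes by edgeR, against 5 by DESeq2 and 3 by limma-voom, and 6 were higher and 1 lower adjusted over the list alone. The alpha subunit gene atp1a1a.5 reached 1657 ± 1115 against 50.3 ± 16.3 CPM and the beta subunit gene ATP1B1_ENSDARG00000013144 3003 ± 1496 against 419 ± 76.8 CPM, whereas atp1a3a was lower at a log2 fold change of -2.27 ± 0.70. Camera called the list higher (median 0.21, adjusted p = 0.0146; adjusted p = 0.555 with an estimated correlation), and its median was -0.47 with library size as the only scaling, which moved the median of all genes from -0.07 to -0.50 and under which the list was still called (adjusted p = 0.00256). That call ended without DL replicate 1 (adjusted p = 0.134), rest replicate 3 (0.0757) or both (0.343, median -0.22).

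Of 30 genes of acid-base transport, 4 were higher adjusted over the list alone, and 0 over all genes by edgeR against 4 by DESeq2, 2 by limma-voom and 4 at an unadjusted p under 0.05. The cytosolic carbonic anhydrase gene ca2 stood at 170 ± 109 against 9.51 ± 2.56 CPM. The ammonia channel gene RHCG_ENSDARG00000100265 stood at 530 ± 348 against 24.4 ± 20.2 CPM, and the anion exchanger gene SLC4A2_ENSDARG00000028173 at 1100 ± 646 against 149 ± 74.7 CPM. Another copy, SLC4A2_ENSDARG00000052330, stood at 19.3 ± 6.95 against 29.1 ± 12.9 CPM and was not called. Camera called the list higher (median 0.15, adjusted p = 0.0379; adjusted p = 0.555 with an estimated correlation), and the median was -0.27 with library size as the only scaling, under which the list was still called (adjusted p = 0.0246). The call ended without DL replicate 2 (adjusted p = 0.105), DL replicate 3 (0.133) or rest replicate 3 (0.347), and without DL replicate 1 and rest replicate 3 together (0.168).

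Among 30 nephron transcription factor genes, 2 were higher over all genes by edgeR, PAX8 and TFAP2B, and 9 adjusted over the list alone, against 8 over all genes by DESeq2 and 1 by limma-voom. GATA3, a factor of the nephric duct lineage, stood at 99.8 ± 46.4 against 18.9 ± 8.18 CPM. Among members with negative changes, lhx1a had a log2 fold change of -3.86 ± 1.82 and did not pass. Camera called the list higher (median 0.92, adjusted p = 2.73e-07; adjusted p = 0.555 with an estimated correlation). Of 13 early distal and collecting duct genes, 1 was higher over all genes by edgeR, against 4 by DESeq2, and 4 were higher and 1 lower, CLDN19, adjusted over the list alone. The early distal list was not called (median 0.12, adjusted p = 0.248), and its median was -0.11 with library size as the only scaling.

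Of 54 claudin and other junction genes, 9 were higher adjusted over the list alone, and 0 over all genes by edgeR, with 11 higher at an unadjusted p under 0.05, 6 by DESeq2 and 1 by limma-voom. The cadherin gene CDH17 stood at 1535 ± 917 against 245 ± 164 CPM and the claudin gene cldn7b at 124 ± 53.6 against 24.8 ± 11.9 CPM. Camera called the list higher (median 0.46, adjusted p = 0.0064; adjusted p = 0.555 with an estimated correlation), but not without DL replicate 3 (adjusted p = 0.0509) or rest replicate 2 (0.0575). Potassium and chloride channels were not called as a list of 61 (adjusted p = 0.85), with a median of -0.46, although 4 were higher adjusted over the list alone. Of these, KCNJ2_ENSDARG00000019418 had a log2 fold change of 3.72 ± 0.64 and ano7 one of 3.03 ± 0.53. Among 45 hormone and growth factor receptor genes, 3 were higher adjusted over the list alone, with the prolactin receptor gene prlrb at 102 ± 83.0 against 9.43 ± 1.84 CPM and erbb3b at 166 ± 73.4 against 23.6 ± 13.1 CPM. At an unadjusted p under 0.05 there were 4 higher and 4 lower receptor genes. The progesterone receptor gene PGR stood at 0.158 ± 0.273 against 5.44 ± 3.61 CPM, and ERBB4_ENSDARG00000090408 had 0 counts in DL and was at least 28.8-fold lower there. DESeq2 called both lower over all genes, and edgeR called neither. The receptor list was not called (median -0.20, adjusted p = 0.854).

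Genes of oxidative metabolism had mostly positive fold changes. Of 99 nuclear genes of the respiratory chain and ATP synthase, 92 were positive, with a median of 0.93 and a camera adjusted p of 1.33e-10 (adjusted p = 0.555 with an estimated correlation). Over all genes edgeR called 0 of them, DESeq2 5 and limma-voom 0, and 15 were higher at an unadjusted p under 0.05. Of these genes cox4i1l stood at 41.1 ± 25.6 against 6.69 ± 3.77 CPM. Camera also called the citric acid cycle (21 genes, median 0.77, adjusted p = 0.000999; adjusted p = 0.58 with an estimated correlation) and fatty acid oxidation (34 genes, median 0.78, adjusted p = 4.99e-05; adjusted p = 0.555 with an estimated correlation). The citric acid cycle call ended without DL replicate 1 and rest replicate 3 together (adjusted p = 0.14). In the latter list the carnitine palmitoyltransferase genes cpt1ab, at 65.2 ± 21.0 against 13.7 ± 1.43 CPM, and CPT1B were higher adjusted over the list alone. All 13 genes matched for the mitochondrial genome by the symbol start mt- were positive (median 0.996, camera adjusted p = 0.0176, and 0.653 with an estimated correlation). The mitochondrial genome call ended without DL replicate 2 (adjusted p = 0.376), DL replicate 3 (0.156) or rest replicate 3 (0.12). Glycolysis (median 0.26, adjusted p = 0.393) and gluconeogenesis with amino acid breakdown (median -0.21, adjusted p = 0.85) were not called, and the glycolysis median was -0.40 with library size as the only scaling.

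Markers of several other cell types were lower as lists, each by the preset-correlation test alone. Of 36 stromal and matrix genes 34 were negative, with a median of -0.95 and a camera adjusted p of 1.5e-07 (adjusted p = 0.555 with an estimated correlation). Both fibronectin copies were lower adjusted over the list alone, FN1_ENSDARG00000006526 at 61.5 ± 50.3 against 459 ± 188 CPM and FN1_ENSDARG00000019815 at 46.2 ± 11.9 against 172 ± 49.0 CPM. Of 38 cell cycle genes 36 were negative, MCM4 and TOP2A among them at -2.24 ± 0.61 and -1.66 ± 0.57, with a list median of -1.39 and an adjusted p of 7.29e-06 (adjusted p = 0.555 with an estimated correlation). Neutrophil and macrophage genes (39 genes, median -0.96, adjusted p = 0.00419; adjusted p = 0.653 with an estimated correlation) and endothelial genes (29 genes, median -0.63, adjusted p = 0.000716; adjusted p = 0.58 with an estimated correlation) were also called lower. So were lymphoid genes (26 genes, median -0.58, adjusted p = 0.0434; adjusted p = 0.609 with an estimated correlation) and blood progenitor genes (19 genes, median -0.43, adjusted p = 0.0422; adjusted p = 0.555 with an estimated correlation). GATA3, also a member of the lymphoid list, was its 1 gene higher adjusted over the list alone. Without DL replicate 1 the adjusted p was 0.475 for myeloid, 0.192 for endothelial, 0.634 for lymphoid and 0.354 for progenitor genes. Without rest replicate 2 it was 0.204 for myeloid, 0.341 for lymphoid and 0.204 for progenitor genes. The lymphoid call also ended without DL replicate 3 (0.0543) or rest replicate 1 (0.0916), and the progenitor call without DL replicate 2 (0.059) or rest replicate 1 (0.132). With library size as the only scaling the adjusted p was 0.0575 for both lymphoid and progenitor genes, and without a low-count filter 0.0803 and 0.11. Without DL replicate 1 and rest replicate 3 together, it was 0.0938 for cell cycle, 0.366 for endothelial, 0.14 for lymphoid and 0.166 for progenitor genes. Multiciliated cell genes were called higher (35 genes, median 0.20, adjusted p = 0.00504; adjusted p = 0.715 with an estimated correlation), with dnai2b at 19.2 ± 3.60 against 7.69 ± 3.37 CPM. That call ended without DL replicate 3 (0.0728), rest replicate 1 (0.0696) or rest replicate 2 (0.779, median -0.16).

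Podocyte genes (18 genes, median -0.60, adjusted p = 0.0544) were not called, with the nephrin gene NPHS1 at 28.8 ± 8.49 against 53.8 ± 10.4 CPM, but they were called lower without rest replicate 3 (0.0494), by limma-voom (0.0182), with a filter of 1 CPM in 3 libraries (0.0463) and after thinning (0.0444). Proximal tubule genes (51 genes, median -0.35, adjusted p = 0.9) were not called either, although 5 members were higher adjusted over the list alone, among them slc9a3.2 and the amino acid transporter gene SLC7A8. Erythroid genes (21 genes, median -0.39, adjusted p = 0.151) were not called but were called lower without DL replicate 3 (0.000482) or rest replicate 1 (0.0114) and by limma-voom (0.0298), and 1 member, tspo, a mitochondrial outer membrane protein gene, was higher adjusted over the list alone. Among 12 genes of neighbouring endocrine and pigment cells (median -0.21, adjusted p = 0.121), the catecholamine synthesis genes DBH and TH had 0 counts in all DL libraries and were at least 72.7-fold and 62.5-fold lower there. The pigment gene pmelb had 0 counts in the rest libraries and was at least 53.6-fold higher in DL, at 2.81 ± 0.486 CPM. All 3 passed in edgeR adjusted over the list alone and not over all genes, where DESeq2 called all 3.

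The WNK kinase and mineralocorticoid list (25 genes, adjusted p = 0.875) was not called; its camera direction was up while its median (-0.04) and mean (-0.05) were negative, and its median was 0.003 with the 20 most abundant genes left out. Magnesium and calcium genes (26 genes, adjusted p = 0.9) had a median of 0.12 and a mean of -0.02, and a median of -0.45 with library size as the only scaling. Cytosolic ribosomal protein genes (95 genes, median 0.10, adjusted p = 0.645) were not called with all libraries but were called without DL replicate 1 (0.00035) and without DL replicate 1 and rest replicate 3 together (0.0129), and their median was -0.30 with library size as the only scaling. That list was matched by a symbol pattern and also held 10 kinase genes such as RPS6KA5, without which the median of the other 85 was 0.13. Immediate-early and heat-shock genes (37 genes, median 0.03, mean -0.02, adjusted p = 0.189) were called lower without DL replicate 3 (0.000105, median -0.98). They were called higher without DL replicate 1 and rest replicate 3 together (0.0475, median 0.54). Their median was -0.19 with library size as the only scaling and -0.02 with the upper quartile. In DL replicate 3 the heat-shock gene hsp70l stood at 5542 CPM, against 395 and 581 CPM in the other DL libraries and 611 to 2797 CPM in the rest.

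**Figure D2:**
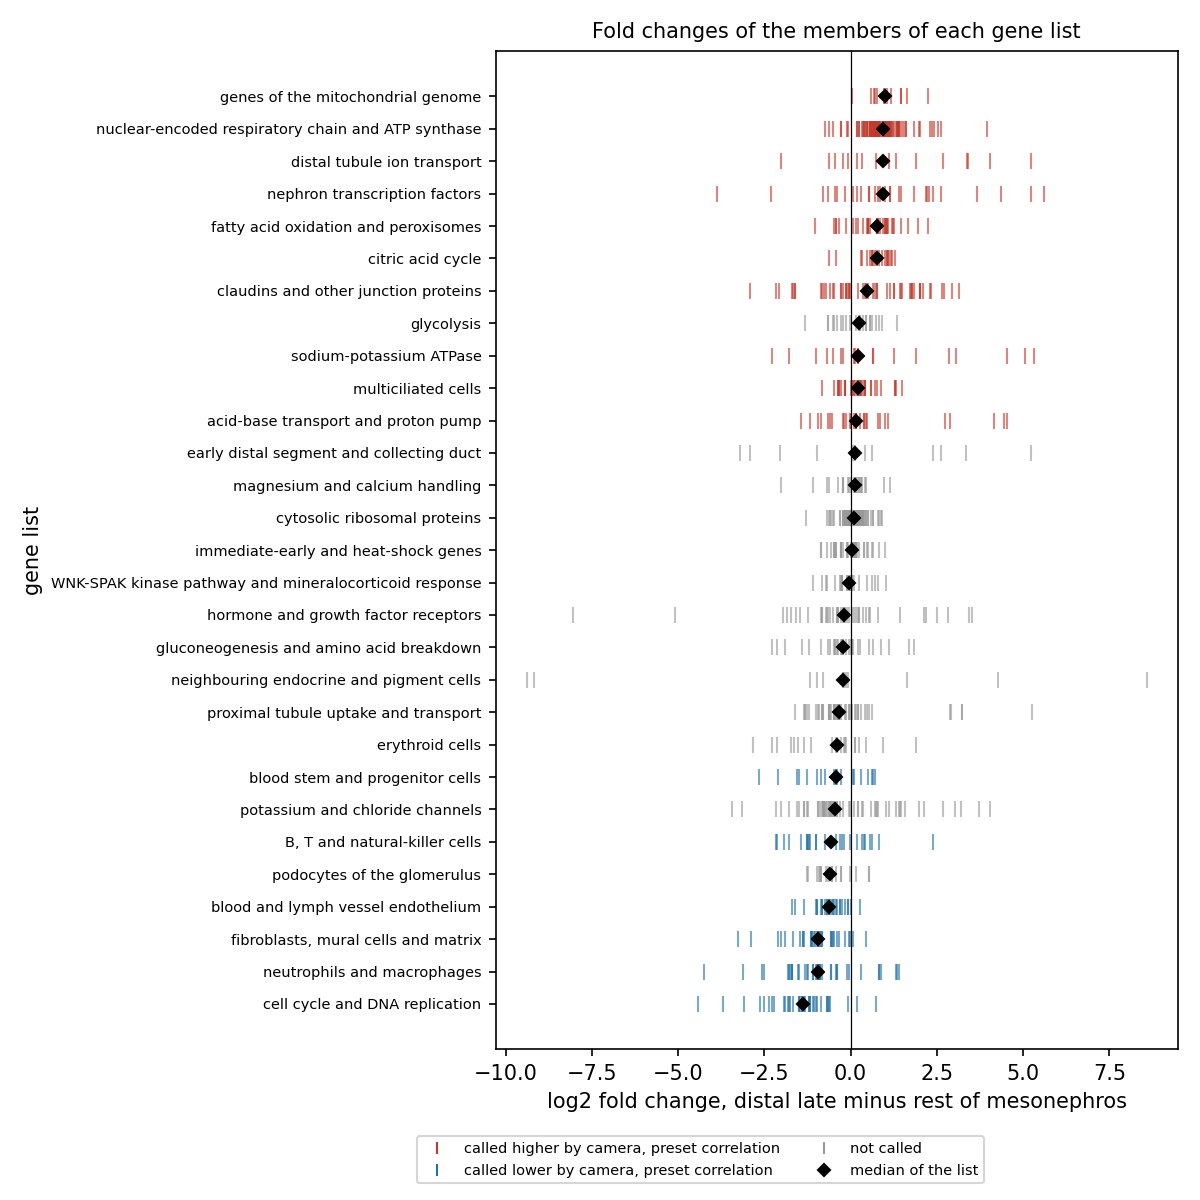
Log2 fold change (DL minus rest) of each tested member of the 29 gene lists, with 1 tick per gene, a diamond at each list's median and colours for the camera result with a preset correlation; genes with 0 counts in a whole group are drawn at their fitted values, which are no bounds. In all, 10 lists were called higher and 6 lower, and 0 were called with an estimated correlation; 7 medians turned negative with library size as the only scaling, which put the median of all genes at -0.50.

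The composition of the libraries differed within both groups. The feature si:dkey-153m14.1 took 38.3% of the counts of DL replicate 1 and 36.9% of those of rest replicate 3, and at most 10.13% in the other 4 libraries. The 13 genes matched for the mitochondrial genome took 2.03% in DL replicate 1 and 2.55% in rest replicate 3, against 8.58% to 18.12% in the other 4. The feature ENSDARG00000080337, which has no symbol and is in no list, took 2.15% and 4.10% in these libraries and 11.9% to 22.2% in the other 4. The 10 largest features took 58.0 ± 16.1% in DL and 52.3 ± 24.3% in the rest (SD, n = 3 each, exact two-sided permutation p = 0.7). The share of counts in sodium pump genes was 0.735 ± 0.482% in DL and 0.169 ± 0.115% in the rest, and that in distal transport genes 0.181 ± 0.17% and 0.032 ± 0.0215%. For both the exact permutation p was 0.1, the smallest that 3 against 3 libraries allow, and 0.954 after adjustment over 31 shares. Shares of the called lists of oxidative metabolism were closer between DL and the rest. They were 0.337 ± 0.237% and 0.258 ± 0.227% for the respiratory chain (exact permutation p = 0.6). For the citric acid cycle they were 0.126 ± 0.0631% and 0.106 ± 0.0766% (0.7). Fatty acid oxidation had 0.082 ± 0.0436% and 0.0762 ± 0.058% (0.9), and the mitochondrial genome 11.4 ± 8.37% and 8.22 ± 5.5% (0.6).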

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

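The removal of DL replicate 1 and rest replicate 3 together, the term for them and DESeq2 without DL replicate 3 were chosen after the data were seen; the other alternatives were planned. With RLE or upper-quartile scaling, a CPM filter, thinning, or the 20 most abundant genes left out, the same 11 genes were called. The counts of genes differing, higher and lower were 314, 235 and 79 in DESeq2 (11 of the 11 genes shared), 36, 36 and 0 in limma-voom (6 shared), and 106, 99 and 7 without a low-count filter (11 shared), where more genes were tested. They were 1, 1 and 0 with library size as the only scaling, and 0, 0 and 0 against a log2 fold change of 1, without DL replicate 1 and rest replicate 3 together, and with a term for them. DESeq2 without DL replicate 3 gave 702, 307 and 395. Over the 6 fits that leave out 1 library, the counts ranged from 0 to 53, from 0 to 51 and from 0 to 2, and the upper ends came without DL replicate 3. The log2 fold changes of the 11 genes were positive in each fit in which they were tested. These genes were called from the same libraries and had every DL library above every rest library, so their constant sign is no independent check.

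The slc12a3 fold change was 3.38 in DESeq2 and 3.94 in DESeq2 without DL replicate 3, past the threshold in both, and ranged from 1.89 to 3.96 over the fits that leave out 1 library. Camera called 10 lists higher and 6 lower, and 0 and 0 with an estimated correlation or by fry, where the smallest adjusted p was 0.258. Leaving out 1 library gave 6 to 10 lists higher and 2 to 7 lower. Without both DL replicate 1 and rest replicate 3, 2 lists were lower, and DESeq2 scaling without DL replicate 3 gave 6 higher. Respiratory chain, fatty acid oxidation, nephron transcription factor and stromal lists were called in 18 of 18 alternatives with a preset correlation. Without both libraries the median of the immediate-early and heat-shock list was 0.54, with the list called higher, and STC1_ENSDARG00000058476 had a log2 fold change of -4.54 in DESeq2 without DL replicate 3, against 4.28 with all libraries. STC1_ENSDARG00000058476 stood at 11225 CPM in DL replicate 3 and at 13.5 and 2.87 CPM in the other DL libraries. Its change of sign thus came with leaving that library out. The causes of the other changes were not tested. Fits that leave out libraries also rest on fewer of them.

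Of 2531 values of named genes under alternatives, 2345 kept their direction or stayed uncalled, 93 gained a call, 92 lost one and 1 reversed, and 81 had another sign. Of 579 list tests 73 lost a call, 12 gained one in the same direction and 1 gained one in the other direction. Shares of counts moved by more than 1 SD in 11 of 203 cases. The CV common to all genes was 76.4% between libraries. Simulated data, drawn with each gene's own dispersion, gave edgeR 8 of 50 genes at 4-fold, which limits what these 6 libraries can show. DESeq2 recovered 21 of these 50 but called 70 unchanged genes, against 6 by edgeR. No paired analysis was possible because the labels number the libraries in 1 series and share no number between groups.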

Other observations

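The tests in this part were chosen after the results were seen; the alternative scalings they draw on were planned. The hormone gene STC1_ENSDARG00000058476 (stanniocalcin) stood at 11225 CPM in DL replicate 3, 32.7 times the next highest library, and at 13.5 and 2.87 CPM in the other DL libraries. In the rest libraries it stood at 343, 228 and 7.79 CPM. The genes nppal, at 214 CPM, and PCSK2, a prohormone convertase at 302 CPM, were also highest in that library, at 13.2 and 4.63 times the next. The immediate-early gene FOSL1 stood there at 511 CPM, 2.71 times the next.

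STC1 is made by the corpuscles of Stannius, endocrine bodies beside the fish kidney, so cells of a corpuscle in that dissection are a candidate explanation. Of CASR and SIM1, the further corpuscle markers in the list fixed in advance, 0 were over 1.5 times higher in DL replicate 3 than in every other library. CASR stood at 6.81 CPM there and at up to 6.33 CPM elsewhere, and SIM1 at 5.96 and up to 8.56 CPM. Both lie above the floor of 3 counts, 0.284 CPM in that library, but the share of corpuscle cells and the level of both genes in them were not measured here, so this source cannot be told apart from another cause. The group labels do not separate this library from the other DL libraries, so its difference from them was not tested. Between the groups STC1_ENSDARG00000058476 had a log2 fold change of 4.28 ± 2.85 (SE) and was not called by edgeR (adjusted p = 0.938).

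The low SLC12A3 in DL replicate 3 raises the possibility of a wrong label. Against it, genes at least 4-fold higher in the other DL libraries than in 2 rest libraries were higher in DL replicate 3 than in the held-out rest library, by a median log2 of 0.98, 2.19 and 1.83 for the 3 held out, with lower quartiles of 0.37, 1.36 and 1.24. Over all tested genes, though, DL replicate 3 was not closer to its own group. Its log-CPM correlated at 0.798, 0.775 and 0.707 with rest replicates 1 to 3. With DL replicates 1 and 2 the correlation was 0.721 and 0.768. Correlation did not follow the labels elsewhere either. DL replicates 1 and 2 correlated at 0.719 with each other, and at 0.722 and 0.7355 with rest replicate 1. With rest replicates 2 and 3 they correlated at 0.608 to 0.702. The whole profile thus cannot decide the label of DL replicate 3. Dilution of DL tissue by other tissue may also lower SLC12A3 there. Over 76 genes, DL replicate 3 lay at a median of 0.232 of the way from the rest mean to the mean of the other DL libraries. These genes ranged from 0.0009 to 0.708, and SLC12A3 lay at -0.0103, below each of them. The set was first drawn at 8-fold (30 genes, median 0.217, from 0.0434 to 0.511), which SLC12A3 does not meet, and was then widened to 4-fold, which it does. The limits in CVs were set with its approximate position known. At the median dilution SLC12A3 would stand at 87.6 CPM, from the lower of the other DL libraries, and its 32.9 CPM lie -1.37 CVs from that (-2.24 from the 163 CPM computed in the same way from the mean of both). An even dilution thus cannot be told apart from a gene-specific difference, because SLC12A3 varies by 71.6% between libraries. That CV came from all libraries, DL replicate 3 included, so the value in question also widens the measure it is judged by. The 76 genes were chosen as high in the other DL libraries, so their median position may be too low.

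The features that fill DL replicate 1 and rest replicate 3 could distort library sizes and so make the fold changes of the 11 genes. A wrong library size moves all genes of a library alike. Over the scalings the median of all genes lay at most 0.50 from 0. The smallest log2 fold change of the 11 genes was 3.67, and their smallest value less 2 SE was 2.63. A common shift of 0.50 is thus smaller than each of these fold changes. DL replicate 1 and rest replicate 3 lie in different groups, though, so their shifts can offset each other in the median of all genes. TMM factors ran from 0.52 in DL replicate 1 to 1.80 in rest replicate 1, so the shift of a single library can be larger. The 11 genes were selected for fold changes large against their SE, so this comparison is no independent test. Distortion of single genes in DL replicate 1 and rest replicate 3 was not tested. How far these libraries act on the number of calls stays open, with 1 gene called with library size as the only scaling and 0 without both.

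The 10 splits of the 6 libraries are too few for a share under 0.05. The real split gave 11 genes and the highest of the others 0, so no other split was as large in total or in the larger direction. At an unadjusted p under 0.05 in edgeR the real split gave 1166 genes. The split of DL replicates 1 and 2 with rest replicate 1 against the remaining libraries gave more, 1256. For lists called by camera the real split gave 16 and no other split was as large. The highest of the others gave 14, from DL replicates 1 and 2 with rest replicate 3 against the remaining libraries.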
